A study of Homo sapiens with 9 samples.

How the data were processed

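RNA sequencing was done on MOLM-13 cells, a human acute myeloid leukemia line, that carried a lentiviral scramble control or 1 of 2 short hairpin RNAs against SMYD3, a SET and MYND domain lysine methyltransferase. Each of the 3 groups had 3 libraries. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra kit. Per the submitters' processing notes, STAR and the hg38 genome were used; their versions, the counting program and the gene annotation are not given in the sources used here, and neither is the strand setting of the counting.

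The authors deposited 1 table of gene counts and 1 table of FPKM values (fragment counts scaled to transcript length and library depth), each with 58735 rows and 9 columns. The deposited counts were whole numbers, summing to between 31428907 and 37602177 per library, and were used as they stood. The deposited FPKM table listed the same rows in the same order; over the 11249 genes with over 50 counts in every library, 99.99% of the ratios of count to FPKM, divided by the gene's ratio in the first column, lay within 1% of a constant for their column. FPKM values were used only for alternatives. Both tables name genes by symbol. Of 57167 distinct names, 57142 were found in GENCODE v29; the others were calendar dates, the form that spreadsheet programs give to some symbols. The 27 rows with date names held 0.102% of counts and were tested but not named. Rows with a repeated name, some of the date rows among them, numbered 1745 (0.0281% of counts) and were treated in the same way. Positions, gene types and transcript GC content were taken from GENCODE v29 on GRCh38.

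The column headers gave the group of each library and no replicate number, so libraries are numbered within a group only as names. The labels do not say whether the 3 libraries of a group came from separate cultures; p-values then measure only the spread between these libraries, which may be technical. Library pairs within a group were compared by a chi-square statistic over genes, which was at least 3.90 per gene for each of the pairs, so none was deposited more than once within a group; pairs across groups were not compared in this way. In each group 1 library stood apart: pairs with scramble library 2, hairpin 1 library 3 or hairpin 2 library 3 had 10.3 to 24.4 per gene, and the pairs without them 3.90 to 4.78.

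Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) after TMM normalization and the default low-count filter, which left 16854 genes. All 9 libraries entered 1 fit with a factor of 3 groups, from which hairpin 1 against scramble, hairpin 2 against scramble and hairpin 2 against hairpin 1 were taken. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors (SE) were taken from the fold change and its F statistic. Levels are given in CPM (counts scaled to library depth with the TMM factors) with the SD over 3 libraries. A total of 33 gene lists were fixed before the data were examined, and the 32 with at least 5 members tested were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01. The list of epithelial and stromal markers had 4 members tested and was left out. An estimated correlation and fry, a rotation test, were run beside it. Fry tests whether the genes of a list move on balance in 1 direction, without comparing them with other genes.

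On simulated counts drawn from the scramble means and the estimated dispersions of the 16854 genes, with a few genes changed alike in both hairpin groups, the test of hairpin 1 against scramble called 38.8% of genes changed by 0.5 on the log2 scale, 65.7% of those changed by 1 and 87.9% of those changed by 2; it called 0.0540% of unchanged genes. For hairpin 2 against scramble the same shares of changed genes were called, and 0.0360% of unchanged genes. Far fewer genes changed in this simulation than were called in the data. The adjusted threshold is laxer where more genes differ, so the shares of changed and of unchanged genes called do not carry over to the data. All hairpin libraries were compared with the same scramble libraries, so 50 sets of counts for unchanged groups were also simulated to show how far shared controls alone make the 2 comparisons alike.

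The rule for genes named in the text was fixed before the data were examined. SMYD3 came first. Other genes had to be protein coding, with a mean of at least 2 CPM, and not on the Y chromosome. For both hairpins it ranked genes by the smaller of their 2 changes and took the first 12 higher and 12 lower, among genes past the threshold with each hairpin in the same direction whose scramble and knockdown libraries did not overlap. For each hairpin it took 6 further genes per direction, and for hairpin 2 against hairpin 1 it took 5 per direction. From each list it took up to 4 members past the threshold with both hairpins in the same direction, or else up to 2 per hairpin with the smallest p. HOXA9, MEIS1, MYC, FLT3, CDK6, BCL2, CD14, ITGAM, CDKN1A and MAP3K2 were named whatever their result. Some genes that the rule takes are left out of the text; the counts of genes and lists include them.

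Alternatives fixed before the data were examined were RLE and upper-quartile factors, no low-count filter, a filter of at least 2 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the 6 libraries compared, leaving out each library, an adjusted p under 0.01, an added minimum of 1 on the log2 scale, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with a minimum of 1 FPKM in 3 libraries, and limma-trend on log2(FPKM + 1) without that minimum. Added after seeing the data were per-library offsets from a smooth on transcript GC content, and a fit without the library of each group whose GC slope lay farthest from its group's median. Genes that share sequence with close copies, such as HSPA1A and HSPA1B, EIF3CL, CBSL, TPSB2, NCF1, HLA genes and ribosomal protein genes with pseudogenes, have uncertain counts, since the treatment of reads that match several places is not given in the sources used here.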

Results

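Gene expression was measured by RNA sequencing in MOLM-13 acute myeloid leukemia cells with a scramble control hairpin or with hairpin 1 or hairpin 2 against SMYD3. The title of the study places SMYD3 downstream of HOXA9, a homeobox transcription factor of leukemic cells, and the comparisons ask which genes differ when SMYD3 is lowered. Each group had 3 libraries. Total counts ranged from 32588647 to 34090854 in scramble, 32252518 to 37602177 in hairpin 1 and 31428907 to 31563871 in hairpin 2 libraries. The first principal component of log2 CPM held 43.5% of the variance and parted scramble from knockdown libraries; the second held 18.3% and parted the hairpins.

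SMYD3 (chromosome 1, 245749342 to 246507312 on GRCh38) had 2596, 2507 and 2565 counts in the scramble libraries. The hairpin 1 libraries had 351, 350 and 368 counts and the hairpin 2 libraries 409, 389 and 316. In CPM the level was 77.0 ± 3.11 (SD, n = 3) in scramble, and 14.2% of that with hairpin 1 and 14.6% with hairpin 2. The log2 fold change was -2.81 (SE 0.110, adjusted p = 1.25e-11) with hairpin 1 and -2.77 (SE 0.110, adjusted p = 1.52e-11) with hairpin 2, from the quasi-likelihood test of edgeR. The hairpins did not differ detectably in SMYD3 (log2 difference 0.04, adjusted p = 0.83).

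HOXA9 and MEIS1, which encode partner homeodomain proteins, fell with both hairpins. HOXA9 (chromosome 7, 27162435 to 27175180) was at 168 ± 10.2 CPM in scramble, 36.0 CPM with hairpin 1 and 35.2 CPM with hairpin 2 (means of 3 libraries; log2 fold changes -2.22 and -2.25). MEIS1 (chromosome 2, 66433452 to 66573869) was at 110 ± 3.63 CPM in scramble, with log2 fold changes of -2.30 and -2.06. MYC (chromosome 8, 127735434 to 127741434), a growth-promoting transcription factor, rose from 248 ± 16.1 CPM to 584 CPM with hairpin 1 and 484 CPM with hairpin 2. CDK6, a cell cycle kinase, rose by 0.83 and 0.71 and the survival gene BCL2 by 0.68 and 0.43. CDKN1A, which encodes the CDK inhibitor p21, fell by 1.35 and 0.94, and the myeloid integrin gene ITGAM fell by 1.64 and 1.45. The receptor kinase gene FLT3, at 3.99 ± 0.229 CPM in scramble, had log2 fold changes of 0.37 (SE 0.177) and 0.03 (SE 0.179), neither past the threshold, and MAP3K2, a kinase known as a SMYD3 substrate, had -0.18 (SE 0.133) and -0.22 (SE 0.133), also short of it. Without scramble library 2, MAP3K2 was past the threshold, at -0.35 (adjusted p = 0.011) and -0.40 (adjusted p = 0.00556), as it was with GC offsets, at -0.46 (adjusted p = 6.19e-05) and -0.41 (adjusted p = 0.000225). CD14 had 38 counts over all 9 libraries and was not tested.

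**Figure D1:**
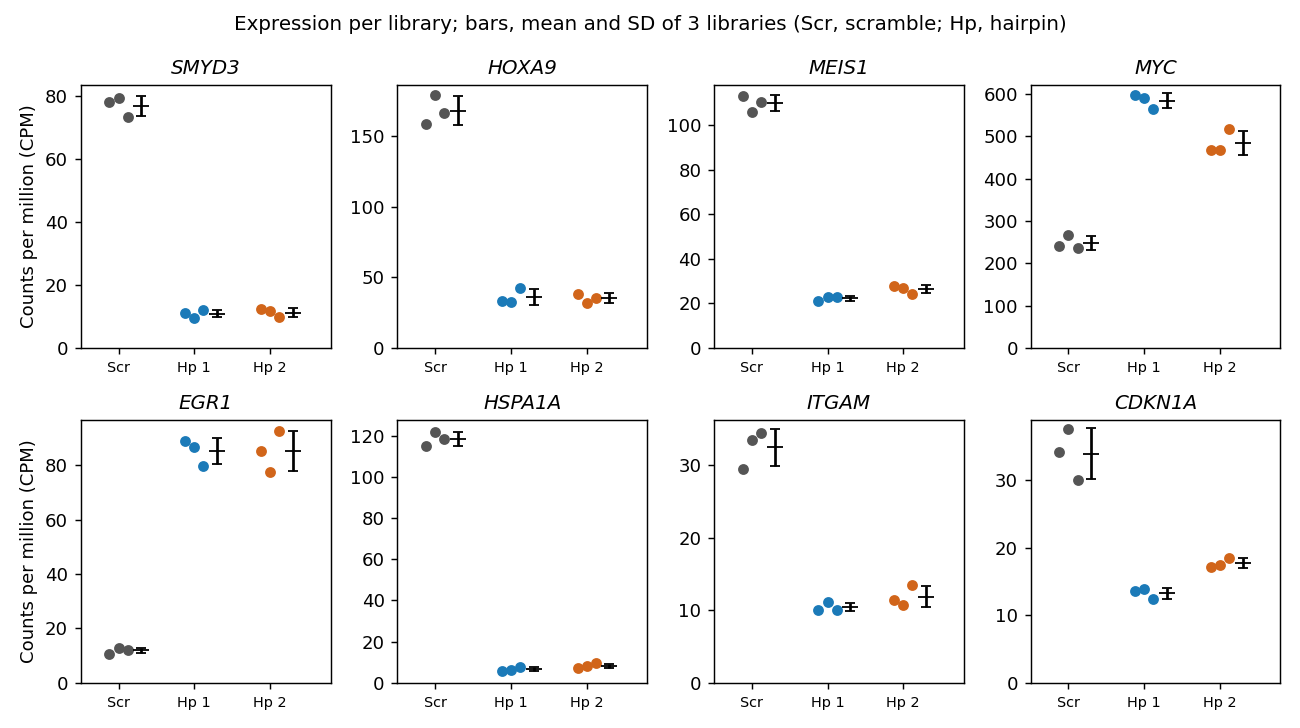
Levels in CPM of 8 genes in each library; points are libraries, bars the mean and SD of 3 libraries, and each vertical axis starts at 0. SMYD3, HOXA9, MEIS1, HSPA1A, ITGAM and CDKN1A lay lower, and MYC and EGR1 higher, in every knockdown library than in any scramble library.

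With hairpin 1, the largest rise among genes of at least 2 CPM that were also past the threshold with hairpin 2 belonged to POU2F2, which encodes the B-cell transcription factor OCT2 (log2 fold change 3.32, SE 0.101, n = 3 libraries per group). The largest fall among them was that of DEFB1, an antimicrobial peptide gene (-5.53, SE 0.411). Against scramble, 3662 genes were higher and 4162 lower with hairpin 1, of 16854 tested, and 537 and 1409 of them by at least 2-fold. The rule for hairpin 1 passed over genes already named for both hairpins, but not other genes that moved with both. It named FTCDNL1, SERPINB10, RGS16, ABLIM1, POLR3G and TTC30B as higher, with log2 fold changes from 1.66 to 1.97. As lower it named KCP, HELZ2, CNR2, ITGAX, GPRIN3 and S100A9, from -3.68 to -3.03. Some of these, such as ITGAX and S100A9, were lower with hairpin 2 as well. HELZ2 encodes a nuclear coactivator helicase, and S100A9 a calcium-binding protein of monocytes and neutrophils.

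With hairpin 2, MASP2, which encodes a complement protease, rose by 2.24 (SE 0.230) and CEP290, a gene of the ciliary transition zone, by 1.90 (SE 0.162). PJVK rose by 1.84, ZNF658 by 1.82 and GPT by 1.76. In all, 3219 genes were higher and 3704 lower than in scramble, of which 700 and 696 changed by at least 2-fold. CBSL, a near copy of CBS, had a log2 fold change of 4.57 with an SE of 1.45 and a level of 8.44 ± 8.17 CPM with hairpin 2 (SD, n = 3); its adjusted p of 0.0456 rose above the threshold without any 1 of the scramble libraries, hairpin 1 library 1 or 2, or hairpin 2 library 1 or 3 (0.0615 to 0.127), and reached 0.329 with limma-voom. Lower were RNASE6 (-3.88), IL1RN (-2.93), OAS1 (-2.72), SGK1 (-2.63), GPRIN3 (-2.62) and KCP (-2.59). RNASE6 was no longer past the threshold without the library of each group whose GC slope was outlying (adjusted p = 0.0789 with hairpin 2).

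EGR1, an immediate early transcription factor (chromosome 5, 138465490 to 138469315), rose by 2.84 (SE 0.0988) with each hairpin, from 11.9 ± 1.05 CPM to 85.1 CPM. POU2F2 rose by 3.32 and 2.75, and IFT57, which encodes an intraflagellar transport protein, by 2.11 and 2.00. HLF, a transcription factor of stem cells, rose by 1.94 and 1.78. In all, 2364 genes were higher and 2853 lower with both hairpins. The rule also named CHML, GDAP1L1, SOCS2, OGDHL, HSPA12B, TNFRSF19, AKAP7 and WWC1 as higher, with changes between 1.57 and 2.11. The inducible HSP70 genes fell with both hairpins, with HSPA6 (chromosome 1, 161524540 to 161526910; -4.81 and -5.10), HSPA1B (-4.52 and -4.16) and HSPA1A (-4.16 and -3.83). HSPA1A and HSPA1B are near-identical neighbours on chromosome 6, and their summed CPM fell by 4.38 and 4.03. NLRP7 fell by 4.36 and 4.06, the chromatin regulator gene ARID5B by 3.81 and 3.89, and DEFB1 by 5.53 and 3.06. SLC12A8, TDRD9, SPSB1, MTUS1 and TMEM150B fell by between 2.85 and 4.37.

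Among genes past the threshold with both hairpins, 1 was higher with hairpin 1 and lower with hairpin 2, and 47 were the reverse. Of all genes tested, 79.2% had the same sign with both hairpins, against a mean of 66.74% in simulations in which unchanged groups shared their scramble libraries. Independent lists of the sizes called with each hairpin would share 699.4 higher and 914.7 lower genes. In the 50 simulations, at most 1 gene was called higher with both and 0 lower (edgeR); at an unadjusted p under 0.05 the mean was 93.5 higher and 73.0 lower, against 2809 and 3253 observed. The Pearson correlation of the 2 log2 fold changes across genes, which are not independent replicates, was 0.75 (Spearman 0.73), against a mean of 0.50 in the simulations. The covariance was 0.426, against 0.0492. The 3 scramble libraries were not split, since both parts could not keep at least 2, and part of the excess may come from sharing them. A further 2559 genes passed with hairpin 1 alone, 804 of which also differed between the hairpins, and 1658 with hairpin 2 alone, 486 of which did. Fold changes fell with transcript GC content (Spearman across genes -0.28 with hairpin 1 and -0.21 with hairpin 2).

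**Figure D2:**
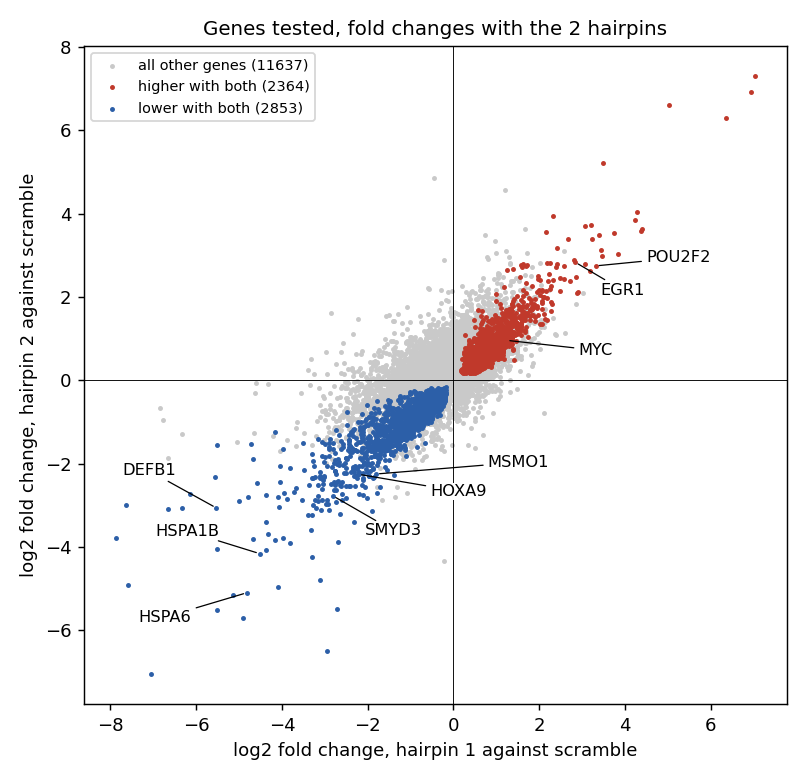
Log2 fold change of each of 16854 genes with hairpin 1 (horizontal axis) and hairpin 2 (vertical axis), both against scramble; red, 2364 genes higher with both, blue, 2853 genes lower with both, grey, all others. Most coloured genes lie near the diagonal, and SMYD3 lies at -2.81 and -2.77.

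Of the 32 lists tested by camera, 3 were higher and 9 lower than other genes with hairpin 1, and 3 higher and 16 lower with hairpin 2. With an estimated correlation, 1 list stayed higher (MYC targets and ribosome biogenesis) and 5 lower with each hairpin: monocyte and macrophage markers, type I interferon response, cholesterol and sterol synthesis, heat shock and cytosolic chaperones, and cell adhesion and homing receptors. Fry called 6 lists higher and 17 lower with hairpin 1, and 6 higher and 23 lower with hairpin 2. Whether a list passed is given below by camera unless fry is named, and some lists that did not pass by camera passed by fry.

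Genes of ribosome production rose. Of 40 MYC targets and ribosome biogenesis genes, 35 were higher with hairpin 1 and 32 with hairpin 2 (35 and 34 adjusted over the list alone), with medians of 0.78 and 0.59 (adjusted p = 7.42e-25 and 1.25e-17; 0.0115 and 0.0218 with an estimated correlation). UTP20 rose by 1.32 and 1.19, ODC1, of polyamine synthesis, by 1.32 and 1.10, TFB2M by 1.25 and 1.09, and NOP58 by 1.08 and 1.00. A single member, EIF4A1, moved in opposite directions (-0.69 and 0.58); it was chosen after its values were seen. Of 74 cytosolic ribosomal protein genes, 68 and 60 were higher and 0 lower (70 and 63 adjusted over the list alone), with medians of 0.69 and 0.40, and RPL7 rose by 1.10 and 0.84. RPS3A, RPL6 and RPL5 rose by between 0.75 and 1.15. These genes held 5.84% ± 0.488 of counts in scramble, 8.84% ± 0.108 with hairpin 1 and 7.89% ± 0.130 with hairpin 2 (SD, n = 3). Their list had adjusted p = 1.92e-37 and 3.7e-16, and adjusted p = 0.15 and 0.235 with an estimated correlation. Of 13 mitochondrially encoded transcripts, 8 and 6 were higher (8 and 6 adjusted over the list alone), led by MT-ND3 (1.12 and 1.01). Adjusted over the list alone, 1 was lower with hairpin 2. This list had adjusted p = 0.000276 and 0.00618, and adjusted p = 0.437 and 0.406 with an estimated correlation; with hairpin 2 it also missed the threshold with GC offsets (0.07). Mitochondrial transcripts held 5.29% ± 0.327 of counts in scramble, 6.69% ± 0.107 with hairpin 1 and 6.46% ± 0.240 with hairpin 2 (SD, n = 3). MT-CYB, MT-ND1 and MT-ND2 rose by between 0.54 and 0.79.

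Monocyte and macrophage markers fell. Of 23 such genes, 15 were lower with hairpin 1 and 16 with hairpin 2, and 2 and 1 were higher (15 and 16 lower adjusted over the list alone; adjusted p = 2.8e-09 and 1.08e-09, and 0.0115 and 0.00692 with an estimated correlation). S100A9 fell by 3.03 and 2.39, the integrin gene ITGAX by 3.12 and 2.34, and CSF1R, the receptor of macrophage growth factor, by 2.35 and 2.13. Granulocyte markers went both ways, with 6 higher and 8 lower with each hairpin (6 and 7 higher and 8 lower adjusted over the list alone): the azurophil granule genes ELANE (1.21 and 1.13) and BPI (1.13 with hairpin 1) rose with both hairpins, while the oxidase subunit gene NCF1 (-1.65 and -1.50) fell. This list did not pass (adjusted p = 0.497 and 0.451). ELANE stood at 1315 ± 149 CPM in scramble and 3050 CPM with hairpin 1. Of 27 adhesion and homing receptor genes, 16 and 18 were lower and 2 each higher (18 each lower, and 4 and 2 higher, adjusted over the list alone). This list had adjusted p = 5.58e-09 and 2.78e-11 by camera (0.0115 and 0.00388 with an estimated correlation). CXCR4, a bone marrow homing receptor, fell by 1.70 and 1.68, the fatty acid receptor gene CD36 by 2.62 and 1.64, and ITGAL by 1.54 and 1.59.

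Of 11 stem and progenitor markers, 5 were higher with each hairpin and 3 and 2 lower (the same counts adjusted over the list alone). HLF, SOCS2 (1.82 and 1.69), KIT, the receptor of stem cell factor (1.53 and 1.52), and CD38 (0.53 and 0.44) rose. The list did not pass by camera (adjusted p = 0.146 and 0.0773), except with hairpin 2 when its library 3 was left out (0.0477). By fry it passed upward with both hairpins (adjusted p = 0.00563 and 0.00409). The HOXA9-MEIS1 program had 11 of 25 members lower with each hairpin and 5 and 4 higher (12 and 11 lower adjusted over the list alone). HOXA5 fell by 0.86 and 0.84 and SOX4 by 0.77 and 0.74. This list had adjusted p = 0.118 with hairpin 1 (0.0235 with GC offsets) and 0.00618 with hairpin 2, the latter 0.266 with an estimated correlation. Of 32 hematopoietic transcription factors, 9 and 6 were higher and 14 and 13 lower (9 and 7, and 14 each, adjusted over the list alone), and the list did not pass (adjusted p = 0.769 and 0.369). KLF6 fell by 1.59 and 1.54, and BCL6 by 1.58 and 1.31. Of 9 lymphoid markers, 5 and 6 were lower (5 and 6 adjusted over the list alone), with adjusted p = 0.0454 and 0.00749, and adjusted p = 0.17 and 0.12 with an estimated correlation. With hairpin 1 it also missed the threshold without scramble library 2 (0.056), hairpin 1 library 1 (0.0503) or hairpin 2 library 3 (0.0542), and with GC offsets (0.0962). It did so too without the 3 libraries of outlying GC slope (0.109). EBF1 fell by 1.53 and 1.44, NKG7 by 0.81 and 0.83 and NCAM1 by 0.72 and 0.61. NCAM1 with hairpin 2 was past the threshold by a small margin, and missed it without scramble library 2 (adjusted p = 0.0557) or hairpin 2 library 3 (0.0565). Of 7 erythroid and megakaryocyte markers, 2 were higher with each hairpin (2 and 4 adjusted over the list alone). With hairpin 1, 1 was lower, and with hairpin 2, 0 were. The transferrin receptor gene TFRC rose by 0.30 and 0.75, the former call ending with GC offsets (0.08, adjusted p = 0.156). The list did not pass (adjusted p = 0.769 and 0.0938; 0.0413 with hairpin 2 and GC offsets). Of the epithelial and stromal markers, PECAM1, which blood cells also express, fell by 0.43 and 0.55, and FN1 by 2.03 and 0.59, the latter lost without scramble library 1 or 3 or any 1 of the hairpin 2 libraries (adjusted p up to 0.119).

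Sterol genes fell. Of 28 cholesterol and sterol synthesis genes, 23 were lower with each hairpin, and 3 and 2 higher (the same counts adjusted over the list alone). The medians were -0.73 and -0.92, with adjusted p = 2.53e-14 and 5e-26 by camera (0.0115 and 0.00388 with an estimated correlation). The sterol methyl oxidase gene MSMO1 fell by 1.81 and 2.25, MVK by 1.45 and 1.42 and EBP by 1.24 and 1.39. Of 30 lysosome and autophagy genes, 24 and 28 were lower and 0 higher (24 and 28 adjusted over the list alone); this list had adjusted p = 1.01e-09 and 1.22e-13, and adjusted p = 0.15 and 0.1 with an estimated correlation. The cathepsin gene CTSD fell by 1.09 and 1.03, and NEU1 and TFEB by between 0.93 and 1.06. Of 30 glycolysis and hypoxia genes, 12 and 18 were lower and 3 each higher (the same counts adjusted over the list alone). Among the lower were PFKFB4 (-1.38 with each), SLC2A3 (-1.15 and -1.35), ENO2 (-1.34 and -1.07) and the pyruvate kinase gene PKM (-0.94 and -1.01). The list had adjusted p = 0.0609 and 0.000412, the latter becoming adjusted p = 0.235 with an estimated correlation. With hairpin 1 it passed without scramble library 1 (0.0418) or 3 (0.021). Oxidative phosphorylation genes had 17 higher and 6 lower with hairpin 1 and 5 higher and 9 lower with hairpin 2 (17 and 6, and 5 and 8, adjusted over the list alone); CYCS rose by 0.89 and 0.60, while SDHA (-0.54 and -0.65) and UQCRC1 (-0.40 and -0.57) fell. COX8A (-0.40 and -0.64) lost its call with hairpin 1 without scramble library 2 (-0.23, adjusted p = 0.094) or hairpin 1 library 3 (0.0654). This list did not pass (adjusted p = 0.0566 and 0.391), but did with hairpin 1 without scramble library 2 (0.00369) or hairpin 1 library 3 (0.0477).

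Of 19 heat shock and cytosolic chaperone genes, 7 were lower with each hairpin and 5 and 4 higher (7 and 9 lower and 5 and 5 higher adjusted over the list alone; adjusted p = 2.73e-07 and 5.83e-12, and 0.0498 and 0.0193 with an estimated correlation). DNAJB1, an HSP70 cochaperone, fell by 1.87 and 2.12 beside the 3 HSP70 genes named above. The list's median was -5.49e-04 with hairpin 1 and -0.15 with hairpin 2. Unfolded protein response genes had 6 and 10 lower and 6 and 3 higher (6 and 10 lower and 6 and 4 higher adjusted over the list alone; adjusted p = 0.947 and 0.142); PDIA4, CREB3L2, SEC24D and HERPUD1 fell by between 0.42 and 0.65. ATF4 and integrated stress response genes had 8 and 4 higher and 5 and 8 lower (9 and 4, and 5 and 8, adjusted over the list alone; adjusted p = 0.299 and 0.451; 0.0235 upward with hairpin 1 and GC offsets). DDIT3, a stress transcription factor, fell by 1.57 and 1.68 and CTH by 0.53 and 0.69, while the amino acid transporter genes SLC7A11 (0.57 and 0.66) and SLC7A5 (0.82 and 0.53) rose.

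**Figure D3:**
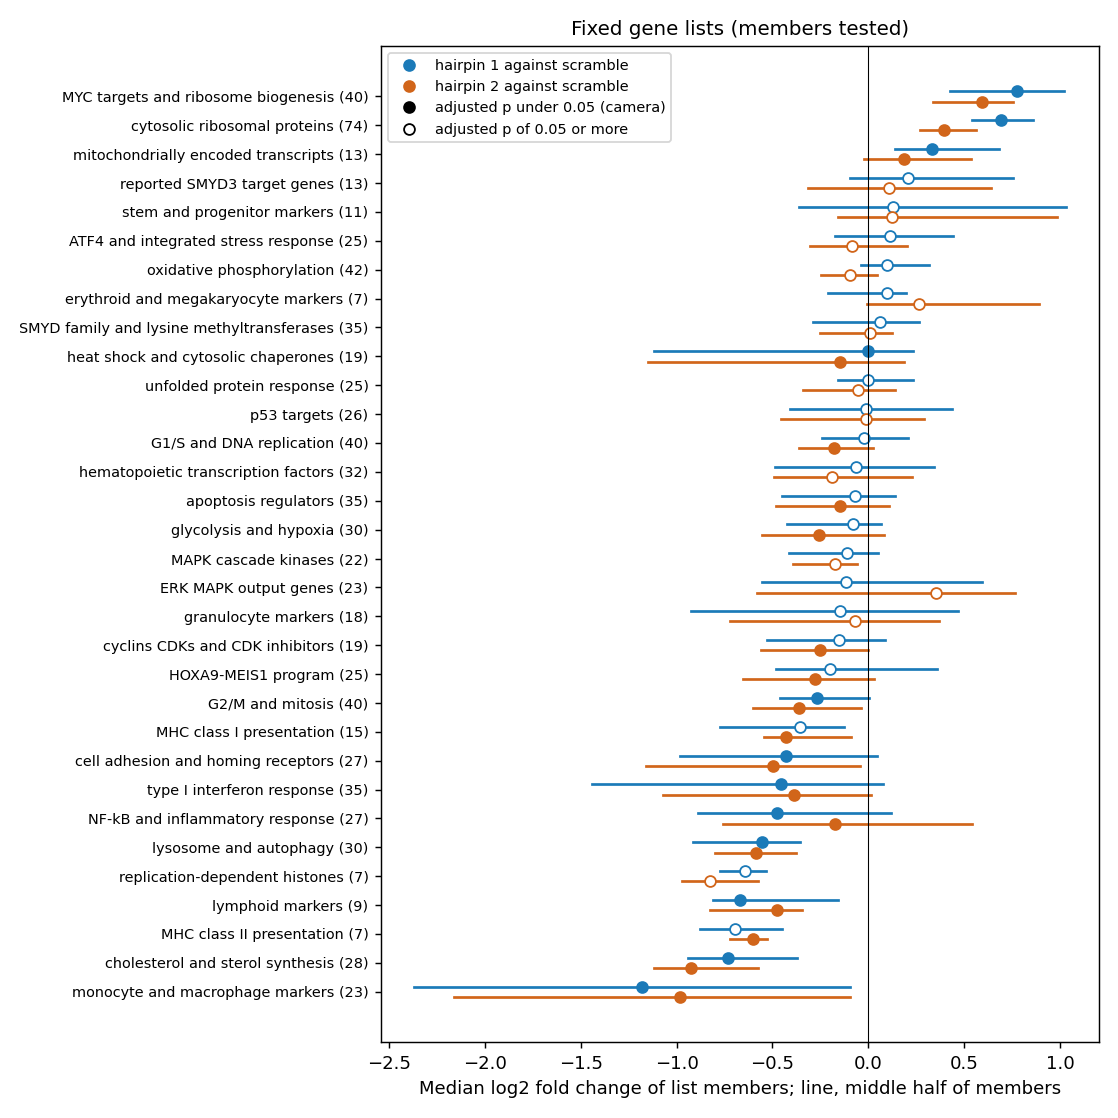
Median log2 fold change of the members of each of 32 fixed lists (points) with the interquartile range of the members (lines), for hairpin 1 and hairpin 2 against scramble; filled points have an adjusted p under 0.05 by camera. MYC targets lie at 0.78 and 0.59 and monocyte markers at -1.18 and -0.98.

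Of 35 type I interferon response genes, 19 and 17 were lower and 5 and 4 higher (19 and 18 lower adjusted over the list alone), with adjusted p = 0.000548 and 0.00164 (0.043 and 0.0455 with an estimated correlation). OAS1, an antiviral enzyme gene, fell by 2.59 and 2.72, IRF7 by 2.24 and 1.71, IFI6 by 1.60 and 1.53 and OAS3 by 1.88 and 1.53. NF-kB and inflammatory genes had 12 and 10 of 27 lower and 4 and 7 higher (12 and 11 lower adjusted over the list alone). IL1RN fell by 2.73 and 2.93, while IL1B, an inflammatory cytokine gene, fell by 1.38 and fell by 2.27. PLAUR fell by 1.33 and 1.26 and TNFAIP2 by 1.08 and 0.95. This list had adjusted p = 0.00425 and 0.0376, and adjusted p = 0.15 and 0.194 with an estimated correlation. With hairpin 2 it also missed the threshold without scramble library 3 (0.0645) or hairpin 2 library 2 (0.0547), and with GC offsets (0.0983). It did so too without the 3 libraries of outlying GC slope (0.0652). MHC class II genes were lower in 6 and 5 of 7. Adjusted over the list alone, 6 each were lower and, with hairpin 2, 1 was higher. The list had adjusted p = 0.055 and 0.0275 by camera, the latter 0.194 with an estimated correlation. CD74 was at -1.01 and -0.94, HLA-DRB1 at -0.74 and -0.83 and CIITA at -1.04 and -0.58. With hairpin 1 the list passed without scramble library 1 (0.0418) or 3 (0.0214), hairpin 1 library 3 (0.0481) or hairpin 2 library 1 (0.0463). With hairpin 2 it missed the threshold without the 3 libraries of outlying GC slope (0.0652). HLA-DMA was at -0.66 and -0.60 (adjusted p = 0.0265 and 0.0448); the former missed the threshold without scramble library 1 or 2 or hairpin 1 library 1 or 3 (up to 0.12), and the latter without scramble library 1 or 2, hairpin 1 library 1 or any 1 of the hairpin 2 libraries (up to 0.16). MHC class I genes were lower in 8 and 9 of 15 and higher in 3 and 2 (9 and 10 lower, and 3 and 2 higher, adjusted over the list alone). The list had adjusted p = 0.0755 and 0.0115 by camera. Without scramble library 3 the former was 0.0214. The latter was 0.266 with an estimated correlation and 0.0569 with GC offsets. TAP1 was at -0.83 for each hairpin, and PSMB9, NLRC5 and HLA-E lay between -0.86 and -0.60.

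Cell cycle genes fell in part. Of 40 G2/M and mitosis genes, 21 and 24 were lower and 3 and 4 higher (21 and 24 lower adjusted over the list alone), with adjusted p = 0.00365 and 1.01e-06, and adjusted p = 0.449 and 0.177 with an estimated correlation. The mitotic kinase genes AURKB (-0.88 and -0.87) and PLK1 (-0.82 and -0.97) fell, as did GTSE1 and CENPA. G1/S and DNA replication genes had 11 higher and 10 lower with hairpin 1 and 3 higher and 16 lower with hairpin 2 (11 and 11, and 3 and 17, adjusted over the list alone; adjusted p = 0.936 and 0.012, the latter 0.182 with an estimated correlation). E2F2 fell by 1.27 and 1.14, E2F1 by 0.79 and 0.75, CDT1 by 0.66 and 0.89 and E2F8 by 0.73 and 0.58. Of 19 cyclin, CDK and CDK inhibitor genes, 6 and 10 were lower and 3 and 2 higher (6 and 11 lower adjusted over the list alone; adjusted p = 0.143 and 0.0312, the latter 0.144 with an estimated correlation): CDKN2D (-1.26 and -1.27), CCNG2 (-1.19 and -1.28) and CCND3 (-1.06 and -0.99) fell, and CCND2 (1.03 and 1.14) rose. Of 26 p53 targets, 8 and 7 were higher and 7 each lower (8 and 7 higher and 7 and 8 lower adjusted over the list alone; adjusted p = 0.864 and 0.702), with BAX at -0.62 and -0.61, TRIAP1 at 0.90 and 0.55 and PHLDA3 at -0.85 and -0.53, the last with adjusted p = 0.0654 for hairpin 2 with GC offsets. With hairpin 1 the p53 list's median was -0.01 and its mean -0.02, while its test pointed up. Of 35 apoptosis regulators, 15 and 13 were lower and 5 each higher (15 each lower adjusted over the list alone). The list had adjusted p = 0.28 and 0.0471 by camera. The latter was 0.151 with an estimated correlation, 0.0539 with RLE factors and 0.1 without the 3 libraries of outlying GC slope. It was 0.0738 without scramble library 3 and 0.0698 without hairpin 2 library 3. BCL2A1, an anti-apoptotic gene, fell by 2.67 and 2.03 and DAPK1 by 0.82 and 0.86; BIK (-0.64 and -0.86) and BIRC3 (0.78 and 1.04) lost their hairpin 1 calls without scramble library 1 (adjusted p = 0.0634 and 0.0542), BIRC3 also without scramble library 2 (0.101) or hairpin 1 library 2 (0.0621), and BIK without hairpin 1 library 1 (0.0805) or 3 (0.0777). Of 7 replication-dependent histone genes, 4 and 3 were lower (4 each adjusted over the list alone; adjusted p = 0.327 and 0.0938, the latter 0.031 without scramble library 1), with HIST1H1C at -0.84 and -1.59 and HIST1H2BK at -0.64 and -0.91, whose hairpin 1 calls were lost without scramble library 2 (adjusted p = 0.0766 and 0.16, the latter at -0.38), that of HIST1H2BK also without hairpin 1 library 2 (0.0784) or 3 (0.0618).

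ERK MAPK output genes had 8 higher with each hairpin and 8 and 7 lower of 23 (8 and 9 higher adjusted over the list alone; adjusted p = 0.221 and 0.192; 0.00423 and 0.00371 upward with GC offsets). EGR1 and FOSL1 (1.27 and 1.12) rose while PHLDA1 (-2.44 and -2.54) and MAFF (-1.64 and -1.61) fell; with hairpin 1 the list's median was -0.12 and its mean -0.00264, while its test pointed up. MAPK cascade kinases had 8 lower with each hairpin of 22 and 3 and 1 higher (the same counts adjusted over the list alone; adjusted p = 0.327 and 0.0624, the latter 0.0223 without scramble library 2 and 0.0262 with GC offsets), with MAP3K3, ARAF, MAPK3 and MAP3K1 between -0.77 and -0.56. The SMYD and lysine methyltransferase list, which includes SMYD3 itself, had 11 and 7 higher and 11 and 9 lower of 35 (the same counts adjusted over the list alone). It had adjusted p = 0.936 and 0.412 by camera. SMYD5 (0.89 and 0.71), SUV39H2 (0.75 and 0.57) and DPY30 (0.67 and 0.49) were higher. The list's medians of 0.06 and 0.01 lay above 0 while its mean and test pointed down with each hairpin. SMYD3, the target of the hairpins, counts among its lower genes and draws its mean down. Reported SMYD3 target genes had 7 and 5 higher and 3 and 5 lower of 13 (the same counts adjusted over the list alone; adjusted p = 0.565 and 0.939): the gelatinase gene MMP2 fell by 1.48 and 1.51, while MYC, WNT10B (0.75 and 0.82) and JAK2 (0.66 and 0.64) rose. For this list with hairpin 2, and for the ATF4 and erythroid lists with hairpin 1, the median and test were positive and the mean negative.

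Hairpin 2 was compared with hairpin 1 to ask where the knockdowns differed. The spermatogenesis gene GGN was at 0.94 CPM with hairpin 1 and 2.74 CPM with hairpin 2 (log2 difference 1.54), the latter near the scramble level of 2.70 ± 0.305 CPM. VCX and FN1 also lay higher with hairpin 2, by 1.46 and 1.43, and DEFB1 by 2.46. Lower with hairpin 2 were IL1B (-0.89), EIF3CL (-0.88), TPSB2 (-0.84), CD302 (-0.70) and PDCD2L (-0.66). EIF3CL was at 22.8 ± 10.5 CPM with hairpin 1 (SD, n = 3). In all, 1183 genes were higher and 1051 lower with hairpin 2, 475 and 8 of them by at least 2-fold. Genes at or under 0.5 CPM had a median log2 difference of 0.59, and genes above 20 CPM one of -0.12. Of the 32 lists, erythroid and megakaryocyte markers were higher with hairpin 2 (adjusted p = 0.0435) and 9 lists lower, led by cytosolic ribosomal proteins (median -0.30, adjusted p = 1.34e-24). These had adjusted p = 0.288 and 0.384 with an estimated correlation, with which 0 lists passed by camera, 5 having an unadjusted p under 0.05, against 14 passing by fry. For the uncalled lists of stem and progenitor markers, ERK output, MHC class I, lysosome, hematopoietic transcription factor and adhesion genes the median and mean had opposite signs.

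The counts between the hairpins depended on single libraries. Higher genes numbered 662, 689 and 657 without hairpin 1 library 1, 2 or 3 and 759 without hairpin 2 library 1. Lower genes numbered 286, 1712 and 439 without scramble library 1, 2 or 3, 318, 400 and 213 without hairpin 1 library 1, 2 or 3, and 441, 544 and 304 without hairpin 2 library 1, 2 or 3. DEFB1, GGN, VCX and FN1 stayed past the threshold in each omission (adjusted p up to 0.0489). IL1B lost its call without hairpin 1 library 1 or 3 or hairpin 2 library 3 (up to 0.0586), EIF3CL, whose difference was -0.44 without hairpin 1 library 3, without hairpin 2 library 3 (0.112) and TPSB2 without hairpin 1 library 3 or hairpin 2 library 1 (up to 0.0861). CD302 lost it without hairpin 1 library 2 or 3 or hairpin 2 library 1 or 3 (up to 0.0693), and PDCD2L without hairpin 1 library 1 or 3 or hairpin 2 library 2 or 3 (up to 0.134).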

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

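The tests of GC content, depth, shared reads and chaperones were chosen after the pattern had been seen; the olfactory receptor test and the counts of other splits were set before their results were seen. The hairpins differed from each other by a test of the difference itself in 1183 higher and 1051 lower genes with hairpin 2. In camera's test of that difference, the lists that were lower with hairpin 2 were cytosolic ribosomal proteins (adjusted p = 1.34e-24), oxidative phosphorylation (9.56e-09), MYC targets (9.7e-06), G1/S genes (1.65e-05), cholesterol genes (0.000182), ATF4 genes (0.000351), G2/M genes (0.0158), the unfolded protein response (0.0208) and glycolysis (0.027), and erythroid and megakaryocyte markers were higher (0.0435). With an estimated correlation 0 of these passed by camera (5 of 32 lists at an unadjusted p under 0.05), and fry called 14 lists. The erythroid list lost its call without any 1 library except hairpin 2 library 1 (adjusted p up to 0.192), G2/M genes without hairpin 1 library 3 (0.0766) or hairpin 2 library 3 (0.193), glycolysis without hairpin 1 library 1 (0.0536) or hairpin 2 library 1 (0.0703) or 2 (0.0732), and the unfolded protein response without hairpin 2 library 3 (0.0545). With GC offsets G2/M genes and the unfolded protein response each lost the call (adjusted p = 0.332), and with fry G2/M genes (0.102) and glycolysis (0.0869) did. Without the 3 libraries of outlying GC slope the erythroid list (0.111), G2/M genes (0.91) and the unfolded protein response (0.139) lost it.

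Among genes under the naming rule, those higher with hairpin 2 than hairpin 1 (log2 differences) were DEFB1 2.46, GGN 1.54, VCX 1.46, FN1 1.43, GPT 1.35, KCP 1.08, MASP2 1.06, TDRD9 1.04, CD36 0.98, HELZ2 0.92, ITGAX 0.78, PJVK 0.75, BCL2A1 0.64, IRF7 0.54, CEP290 0.52, TFRC 0.45, CDKN1A 0.41, HSPA1B 0.36 and OAS3 0.35. Those lower were IL1B -0.89, EIF3CL -0.88, TPSB2 -0.84, CD302 -0.70, PDCD2L -0.66, POU2F2 -0.57, RGS16 -0.48, MSMO1 -0.44, SERPINB10 -0.39, RPS3A -0.38, TRIAP1 -0.35, RPL5 -0.34, RPL6 -0.30, CYCS -0.29, SLC7A5 -0.29, MYC -0.27, RPL7 -0.27, DNAJB1 -0.25 and ODC1 -0.22. Of the 40 genes under the naming rule that differed between the hairpins, not all of which are given here, 15 stayed past the threshold when any 1 of the 9 libraries was left out, among them CD36, FN1, BCL2A1, TFRC, POU2F2 and RPS3A. The other 25 lost the call without at least 1 library, any but scramble library 2, with adjusted p up to 0.19; MYC lost it in 5 omissions (up to 0.0772). In proportion to their size, the differences of EIF3CL and MSMO1 shrank most. That of EIF3CL was -0.44 without hairpin 1 library 3, and that of MSMO1 -0.26 without hairpin 2 library 3 (adjusted p = 0.0994). In log2 units that of DEFB1 shrank most, from 2.46 to 1.86.

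For the genes that moved in 1 direction with both hairpins, 100 splits of the 840 were used, the real one included. The real one alone gave 5217 genes, and the highest other gave 3 (edgeR). At an unadjusted p under 0.05 the real one gave 6062 and the highest other 2083. Splits that mix the groups move differences between groups into the spread within them, so few adjusted calls were likely beforehand. Chance is thus not excluded by the adjusted counts. Nor can any split tell a SMYD3 effect from a difference between cultures. For the correlation across genes, 9 of 100 splits gave a value as high as 0.75, the real one included. The highest other gave 0.86. Where groups are mixed, real differences enter the shared reference and can raise the correlation. These splits therefore cannot decide whether chance explains it. Single comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. There the real split gave 7824 genes with hairpin 1, 6923 with hairpin 2 and 2234 between the hairpins, and the highest other 0, 0 and 1 (edgeR). At an unadjusted p under 0.05 the real split gave 8885, 8159 and 5065, and the highest other 736, 1269 and 1775. For lists, the real split gave 12, 19 and 10, and the highest other 9, 12 and 10.

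Fold changes against scramble fell with transcript GC content (Spearman across genes -0.28 with hairpin 1 and -0.21 with hairpin 2). GC bias as the whole cause of the shared calls is argued against by the offsets, which kept 85.8% of them. A GC bias that differs between libraries stays open as a source of the trend itself: within a group, GC slopes spanned up to 1.14 times the gap between scramble and knockdown means. This ratio rests on single libraries, being 0.77 without hairpin 2 library 3, 0.97 without scramble library 3 and 1.57 without scramble library 2, and the gap itself, 0.193 in log2 per 10% of GC, had an exact two-sided p = 0.0476 over 84 splits. An effect of SMYD3 on genes of high GC content is also open and was not tested.

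Genes of low abundance lay lower with hairpin 1 than with hairpin 2: at or under 0.5 CPM the median log2 difference was 0.59, against -0.12 above 20 CPM. Against scramble, the medians at or under 0.5 CPM were -0.405 with hairpin 1 and 0.168 with hairpin 2. Unequal depth does not account for the difference between the hairpins, since its median was 0.58 after thinning all libraries to the smallest total. Totals differed little before thinning. With GC offsets the median was 0.65, but the offsets were fitted on genes of at least 5 CPM. They cannot decide on a GC bias particular to rarer genes. A background of genomic DNA may contribute and cannot be told apart: summed olfactory receptor CPM was 1.33 times higher with hairpin 2, between the bounds set for either reading, on 86 to 153 counts per library. An effect particular to 1 hairpin is open and untested.

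HSPA1A, HSPA1B and HSPA6 fell with both hairpins. GC content does not explain this, since the weakest of the 6 log2 fold changes was -3.61 with GC offsets, nor do reads shared between HSPA1A and HSPA1B, since their summed CPM had a log2 fold change of at most -4.03. A general heat shock response in the scramble cultures cannot be told apart: 25% of the other 16 chaperone genes were lower with both hairpins, 4 genes, while 4 were higher, which is neither over 50%, the bound set for such a response, nor under 25%, the bound set against it. The state of the cultures is confounded with the groups, and a SMYD3 effect on these genes is open.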

How the results depend on the processing

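GC offsets and the fit without 3 libraries of outlying GC slope (scramble library 2, hairpin 1 library 3 and hairpin 2 library 3) were chosen after seeing the data. SMYD3 stayed lower and past the threshold in every alternative, from -2.89 to -2.73 with hairpin 1 and -2.84 to -2.66 with hairpin 2 when 1 library was left out. Leaving out 1 library gave 2982 to 3694 higher and 3567 to 4614 lower genes with hairpin 1, 2625 to 3383 and 3109 to 3728 with hairpin 2, and 2004 to 2539 and 2505 to 3030 with both. A 2-fold minimum left 537 and 1409 with hairpin 1, 700 and 696 with hairpin 2, and 282 and 592 with both, by construction; other alternatives stayed within 1.5 times for these 6 counts. The difference between the hairpins moved most. Higher genes, 1183, numbered 428 at an adjusted p under 0.01, 475 with a 2-fold minimum, 726, 705 and 349 with log2(FPKM + 1), log2(FPKM + 0.1) and log2(FPKM + 1) without a filter, 2155 with GC offsets, 1968 without the outlying libraries, and 657 to 1359 when 1 library was left out. Lower genes, 1051, numbered 123 at an adjusted p under 0.01, 8 with a 2-fold minimum, 158 with unfiltered FPKM, 228 with upper-quartile factors, 403 with the stricter filter, 2367 without the outlying libraries, and 213 to 1712 when 1 was left out, each of the 9 moving it by over 1.5 times. The share of higher calls there, 53% by default, was 85.5% with upper-quartile factors, 71.6% with the stricter filter and 64.4% with GC offsets, but 39.7% and 39.3% with log2(FPKM + 1) and log2(FPKM + 0.1), 45.4% without the outlying libraries and 44.3% to 78.7% without 1 library, so the balance of directions was not stable. Lists past the threshold numbered 31 over both hairpins (12 and 19), 12 (6 and 6) with an estimated correlation and 52 (23 and 29) with fry; without 1 library 30 to 34 (11 to 15 and 17 to 20). Between the hairpins 10 lists passed, 7 to 10 without 1 library and 0 with an estimated correlation by camera, where 5 had an unadjusted p under 0.05, and fry called 14. The correlation across genes, 0.75 (jackknife SE 0.0762), was 0.56 without a filter, 0.86 with the stricter filter, 0.84 with log2(FPKM + 1) and 0.68 to 0.76 without 1 library. For the other named genes a tally was made without the unfiltered log2(FPKM + 1) fit. A change of sign with no call in either fit counted as no change. Of 9903 values over alternatives, 9580 kept their side of the threshold, 240 lost a call, 81 gained one and 2 reversed. Those 2, and 2 lists, did so for hairpin 2 against hairpin 1 without the outlying libraries: BAX to -0.24, CTSD to -0.16, granulocyte markers to a call downward (adjusted p = 0.0156) and G2/M genes to an upward direction that did not pass (0.91). The cause of these moves was not tested. No paired analysis was possible because the columns carry no replicate numbers, so the planned blocked fit was not run. In simulated data 38.8% of genes changed by 0.5 on the log2 scale were called, over genes of all abundances. Far fewer genes changed there than were called in the data, so that share does not carry over to the data.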

Other observations

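The test of cilium genes was set before its result was seen, on a list prompted by IFT57, TTC30B and CEP290, which had been seen higher; the run without those 3 was chosen after it, and symbol families and gene types were looked at after the data had been seen.

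Genes of the primary cilium, a sensory projection of the cell surface, lay higher as a group. Of 51 cilium assembly genes tested, 23 were higher with hairpin 1 and 22 with hairpin 2, with 19 higher with both and 0 lower with both; 3 were lower with hairpin 1 and 0 with hairpin 2. The medians were 0.36 and 0.37. Camera gave a larger p of the hairpins of 4.66e-06, upward with each, and p = 0.0194 and 0.0112 with an estimated correlation. Without IFT57, CEP290 and TTC30B, 16 of 48 were higher with both, and the larger p was 0.000481 (0.0488 and 0.0288 with an estimated correlation). Cilium genes may thus rise as a set when SMYD3 is lowered, a hypothesis found and tested on the same data. The list was not run with GC offsets. The fall of fold changes with transcript GC content may therefore contribute, which was not tested.

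Some non-coding classes lay higher with hairpin 2 than with hairpin 1; no class was tested as a set. Of 1181 antisense genes tested, 272 were lower and 99 higher with hairpin 1, while 78 were lower and 173 higher with hairpin 2, and 120 were higher and 2 lower with hairpin 2 than hairpin 1. Sense intronic genes showed 51 lower and 3 higher with hairpin 1, and 17 lower and 11 higher with hairpin 2. The median log2 differences of antisense and sense intronic genes, hairpin 2 minus hairpin 1, were 0.455 and 0.60, near those of all genes at or under 0.5 CPM (0.59) or from there to 2 CPM (0.38), so low abundance may account for them, which was not tested. Processed pseudogenes, 848 tested, did not share this, with 40 higher and 49 lower with hairpin 2 than hairpin 1 (median -0.03). Without a stated strand setting, reads of antisense and sense intronic genes cannot be parted from those of the genes they overlap.

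Of 105 families of protein-coding genes sharing a symbol stem, 18 passed with hairpin 1 and 6 with hairpin 2 by camera; with an estimated correlation the lowest adjusted p was 0.397 and 0.341, so no family passed. The families below were picked from these after their values were seen. The stem COL, that of collagen genes, had 12 of 23 members lower and 1 higher with hairpin 1. With hairpin 2 it had 9 lower and 3 higher (camera adjusted p = 0.00552 and 0.375). Its members were not checked singly to be collagens. Matrix metalloproteinase genes had 6 of 12 lower with hairpin 1 and 5 with hairpin 2, the latter beside 1 higher (adjusted p = 0.00582 and 0.0452). With an estimated correlation hairpin 1 had adjusted p = 0.397 for the stem COL and 0.418 for matrix metalloproteinase genes. Hairpin 2 had 0.532 for the latter. Mitochondrial ribosomal protein genes of the large subunit had 22 of 49 higher and 2 lower with hairpin 1, and 14 higher and 8 lower with hairpin 2 (adjusted p = 0.000644 and 0.437; with hairpin 1, adjusted p = 0.486 with an estimated correlation).

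FLT3 was at 3.99 ± 0.229 CPM in scramble, low for a line known for a FLT3 mutation. Whether this lies in the cell stock or in the counting of reads was not tested.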
